A study of Homo sapiens with 12 samples.

How the data were processed

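RNA was measured in 12 libraries of the human embryonic stem cell line ESI017 carrying the SOX2::mCitrine reporter. Per the labels' protocols, messenger RNA was selected by its poly-A tail, copied to cDNA from random hexamers and sequenced as paired ends on an Illumina instrument, and no strand setting is given in the sources used here. Salmon and the genome build GRCh38 are named, per the submitters' processing notes, with no Salmon version, annotation release or bias correction. The table the authors deposited holds estimated counts per gene, which were not scaled between libraries, and 1 column belongs to each library. The column totals were 16474856 to 28079048 estimated counts.

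The estimated counts were rounded to whole numbers. The table has 37951 Ensembl identifiers with 35940 symbols, and 1034 symbols stand on more than 1 identifier, mostly alternate copies of a locus among which the counting can split reads. Each identifier was kept as deposited, a choice settled after counts with identifiers apart and summed had been seen. GENCODE 29 on GRCh38, which held 35003 of the identifiers, gave the coordinates, GC content and transcript lengths. Of the 17706 identifiers tested, 1239 belong to symbols with several identifiers, and so did 166 of the 3858 calls between the gates. Overlapping and antisense genes are equally uncertain without a stated strand.

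Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filter filterByExpr by group (minimum count 10, minimum total 15) and the quasi-likelihood test (glmQLFit and glmQLFTest), two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. All 12 libraries entered 1 model with a mean for each of 7 groups, which leaves 5 residual degrees of freedom besides a prior of 4.4. The comparisons were SOX2-negative against SOX2-positive averaged over 100 and 1000 ng/ml, each gate at each of these doses against control, 1000 against 100 ng/ml within each gate, and the difference of that dose effect between the gates. The model had no term for the repeat.

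Groups and replicate numbers come from the sample titles. The series description calls the second set a biological repeat, so p-values measure the spread between these repeats of 1 cell line. It also gives the pairing, since both gates of a dose and repeat came from the same colonies and each repeat was a separate run. No fit modelled the colonies, so gate p-values do not rest on paired differences. As a check, deviations of same-numbered libraries from group means correlated at -0.01 to 0.17 over 10 pairs of groups, 5 over 0.1. These are across genes, which are not independent. Call counts with the repeat as a block had been seen when the pairing was judged, and the main model stayed as planned. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 24.9 to 146.9, so none was counted as 1 library.

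The 27 gene lists were pluripotency, forebrain, midbrain and hindbrain, neural progenitor, HOX groups 1 to 4, 5 to 9 and 10 to 13, neuromesodermal and caudal, primitive streak, presomitic and somitic, lateral and cardiac mesoderm, definitive endoderm, neural crest, surface ectoderm and amnion, endothelial and blood, WNT targets, FGF targets, Nodal pathway, BMP, retinoic acid, Notch, epithelial, mesenchymal, glycolysis and hypoxia, cell cycle, dissociation stress and mitochondrially encoded genes. Some genes stand in more than 1 list. They were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, again with an estimated correlation, and with Benjamini-Hochberg adjustment over the lists of a comparison. The groups, the model, the lists, the alternatives and the rule for named genes were fixed before the data were examined, except the choice to keep identifiers apart, their summing, the testing of lists in the difference between gates and that of lists with each library left out, which were chosen after seeing the data.

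The rule for named genes took 26 fixed genes, up to 10 called genes per direction and comparison with the highest fold change, and up to 4 called members per list. The second kind needed a mean of at least 5 CPM in the higher group and every library of one group above every library of the other, and left out clone-based names, mitochondrial genes and those of the sex chromosomes that tell sexes apart. Some genes that the rule took are not reported here. Other genes named are marked as chosen after their values were seen. Where a group had no count, a fold is a lower bound against 3 counts over the group. Such floors cover counting error only.

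The tests were tested on simulated data with the real genes, means and library sizes. For SOX2-negative against SOX2-positive (17194 genes) edgeR recovered 34.3% of genes changed 2-fold, 68.7% of those changed 4-fold and 71.2% of those changed 8-fold. For SOX2-positive cells at 100 ng/ml against control (17171 genes) the shares were 6%, 52.2% and 71.2%, for dose in SOX2-positive cells (17174 genes) 4.5%, 70.1% and 65.2%, for dose in SOX2-negative cells (17182 genes) 4.5%, 44.8% and 65.2%, and for the difference between gates (17170 genes) 0%, 35.8% and 74.2%. Unchanged genes made up 6 of 122, 4 of 90, 5 of 98, 8 of 84 and 11 of 84 calls in the same order, and 7 of 100, 3 of 93 and 5 of 81 in the other comparisons with control, at a threshold meant to admit 5%. Between the gates camera called the changed list and 0 of 100 unchanged lists, which is no test on correlated genes.

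The alternatives were DESeq2 size factors in place of TMM, no filter on low counts, the Wald test of DESeq2 1.42.0, limma-trend, the repeat as a block, only the groups compared in the fit, the fit without the 300 ng/ml libraries, 3 doses averaged between the gates, each library left out in turn and identifiers summed by symbol. No correction for GC content or length was applied to the tested counts.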

Results

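Human embryonic stem cells of the ESI017 line, carrying an mCitrine reporter on SOX2, were grown as colonies confined to micropatterns, printed adhesive areas of fixed shape. For 3 days the colonies were kept in N2B27, a serum-free neural basal medium, either alone (control) or with FGF8 at 200 ng/ml and WNT3A at 100, 300 or 1000 ng/ml. The treated colonies were dissociated and sorted by the reporter into SOX2-positive and SOX2-negative cells, and their RNA was sequenced. The series title names the question, how endogenous Nodal signalling shifts the reading of WNT from posterior patterning to germ layer differentiation. No library here carries a stated change of Nodal. There were 12 libraries, 2 for control and for each gate at 100 and 1000 ng/ml (WNT3A 100 and WNT3A 1000), and 1 for each gate at 300 ng/ml. Values are CPM, counts scaled to an equal library total after TMM adjustment of that total. They are given as mean ± SD over the 2 libraries of a group, or over 4 libraries where both doses are pooled.

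The first principal component held 41.2% of the variance and set the SOX2-negative libraries (74.5 to 92.5) apart from the SOX2-positive and control libraries (-70 to -45.7). The second held 15.3% and separated the controls (65.7 and 87.4) from the SOX2-positive libraries (-49.5 to -17.3). WNT3A 100 SOX2-negative replicate 2 lay at 58 on this component, while the other SOX2-negative libraries lay at -18.6 to 0.4.

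**Figure D1:**
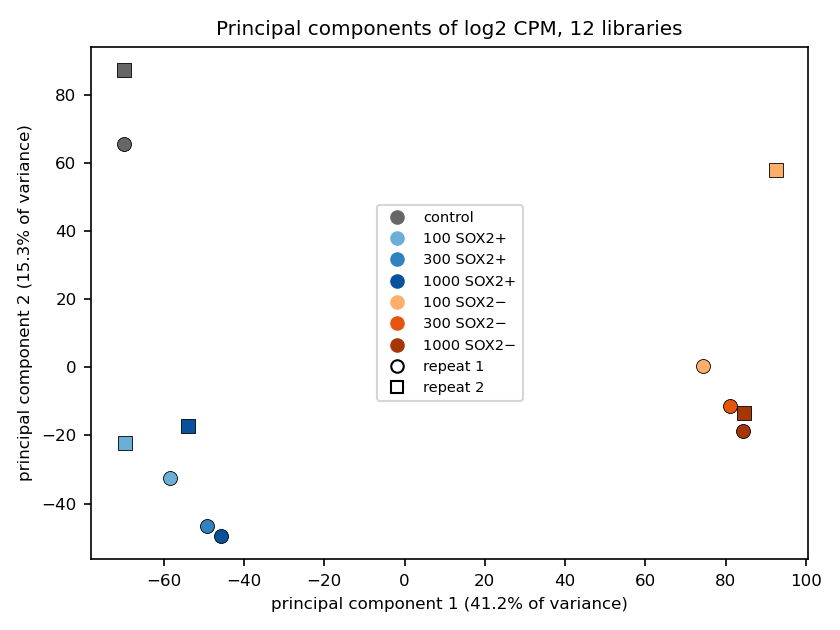
Each point is 1 library, placed by its first and second principal components of log2 CPM (arbitrary units, share of variance on each axis), coloured by group, with circles for repeat 1 and squares for repeat 2. The SOX2-negative libraries lie at 74.5 or higher on the horizontal axis and all others at -45.7 or lower.

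The first comparison asked how the cells that had lost the SOX2 reporter differed from those that kept it, averaged over 100 and 1000 ng/ml. SOX2 (ENSG00000181449, chromosome 3, 181711924 to 181714436, GRCh38), the gene of the sort, stood at 666 ± 17.6 CPM in control, 438 ± 23.5 CPM in the SOX2-positive libraries (n = 4) and 4.06 ± 1.88 CPM in the SOX2-negative libraries (n = 4). This checks the gates and is no finding. The endoderm regulator SOX17 (ENSG00000164736, chromosome 8, 54457935 to 54460888) was higher in the SOX2-negative libraries, at 539.8 ± 204 against 4.16 ± 2.94 CPM (log2 fold change 7.11 ± 0.40 SE, adjusted p = 1.4e-05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Fibronectin, FN1 (ENSG00000115414, chromosome 2, 215360440 to 215436172), reached 8356 ± 3787 against 339 ± 134 CPM (adjusted p = 2.8e-06, edgeR). EOMES (ENSG00000163508, chromosome 3, 27715949 to 27722711), a regulator of the primitive streak and endoderm, stood at 220.5 ± 112 against 19.9 ± 19.9 CPM (adjusted p = 0.0022, edgeR). The forebrain regulator LHX5 fell from 24.6 ± 22.1 to 0.478 ± 0.541 CPM (adjusted p = 0.0016, edgeR). FOXD3, a gene of pluripotent cells and of neural crest, fell from 35.1 ± 5.59 to 0.269 ± 0.141 CPM (adjusted p = 7.2e-06, edgeR).

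Of 17706 genes tested, counted by Ensembl identifier, 3858 were called at an adjusted p under 0.05 by edgeR, 2055 higher and 1803 lower in the SOX2-negative libraries. Among those with the highest rise were the homeobox genes MNX1 (12.1 ± 7.56 against 0.208 ± 0.307 CPM) and PITX1 (19.2 ± 8.32 against 0.0945 ± 0.0634 CPM). So were the hedgehog ligand IHH (12.1 ± 4.75 against 0.0700 ± 0.0874 CPM), CRHBP and PLCXD3. Among those with the deepest fall were HES3 (0.184 ± 0.224 against 27.4 ± 11.6 CPM) and the keratin KRT7 (0.112 ± 0.0779 against 15.7 ± 6.13 CPM). The tryptophan-catabolising enzyme IDO1 (0.563 ± 0.154 against 75.5 ± 30.0 CPM), MGAT4C, TRIML2, LMO1 and TRPM3 were there too. LHX1, DOC2B and PRSS2 have several identifiers that share reads, and an identifier of each was among the highest rises. Summed, LHX1 stood at 3.79 ± 0.260 and 6.15 ± 2.49 CPM in SOX2-positive cells at 100 and 1000 ng/ml against 169.8 ± 56.7 and 249 ± 132 CPM in SOX2-negative cells. All 3 rose between the gates with identifiers summed (adjusted p = 2.3e-06, 6e-06 and 1.4e-05, edgeR). BTBD7, with an identifier called higher, was not called summed (adjusted p = 0.58, edgeR), and was called lower on leaving out WNT3A 100 SOX2-negative replicate 1 (adjusted p = 0.039). GP1BB, which overlaps a neighbouring gene, was among the highest rises and is uncertain. The count of called genes was 2388 without WNT3A 100 SOX2-positive replicate 2, 2570 without WNT3A 1000 SOX2-positive replicate 2 and 6512 without WNT3A 100 SOX2-negative replicate 1.

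Of the 11 measured genes of the definitive endoderm list, 10 rose and 0 fell (10 higher adjusted over the list alone, camera adjusted p = 4.8e-09, adjusted p = 0.03 with an estimated correlation). Among 27 lists, 16 had a camera call here, and only definitive endoderm kept it with an estimated correlation. GATA6 rose by 6.18 ± 0.52 (SE) on the log2 scale, FOXA1 by 5.78 ± 0.53 and PRDM1 by 5.77 ± 0.25. FOXA2 reached 195 ± 62.3 against 4.64 ± 2.19 CPM. In the lateral and cardiac mesoderm list 10 of 11 rose (11 higher adjusted over the list alone, camera adjusted p = 6.4e-09, adjusted p = 0.086 with an estimated correlation). Among them TBX3 stood at 166 ± 71.4 against 2.62 ± 2.36 CPM and HAND1 at 69.1 ± 74.1 against 1.75 ± 2.75 CPM. In the primitive streak list 7 of 11 rose (8 higher adjusted over the list alone, camera adjusted p = 4.3e-07, adjusted p = 0.19 with an estimated correlation). The receptor gene APLNR reached 513 ± 192 against 11.7 ± 6.89 CPM. The streak genes TBXT (26.0 ± 23.2 against 10.1 ± 11.4 CPM, adjusted p = 0.2) and MIXL1 (43.7 ± 45.5 against 6.86 ± 8.33 CPM, adjusted p = 0.066) did not pass edgeR's test. Both passed edgeR's test with the repeat as a block (adjusted p = 0.029 and 0.00039) or with no filter on low counts (2.8e-08 and 1.4e-29). MIXL1 also passed by DESeq2 (adjusted p = 0.036) and by edgeR with identifiers summed (adjusted p = 0.045). MIXL1 gained the call without WNT3A 1000 SOX2-positive replicate 1 or WNT3A 100 SOX2-negative replicate 2 (edgeR adjusted p = 0.038 to 0.04). In the mesenchymal list 9 of 13 rose (9 higher adjusted over the list alone, camera adjusted p = 4.3e-07, adjusted p = 0.086 with an estimated correlation). N-cadherin, CDH2, stood at 723 ± 126 against 78.5 ± 11.0 CPM.

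Among targets of WNT signalling 8 of 12 rose (9 higher adjusted over the list alone, camera adjusted p = 6.4e-07, adjusted p = 0.086 with an estimated correlation). SP5 stood at 318 ± 129 against 23.9 ± 17.4 CPM and was called. AXIN2 stood at 57.1 ± 22.9 against 42.6 ± 5.88 CPM (adjusted p = 0.32, edgeR). Of the FGF targets 8 of 12 rose and 1 fell (8 higher and 1 lower adjusted over the list alone, camera adjusted p = 2e-04, adjusted p = 0.31 with an estimated correlation). The ERK phosphatase DUSP6 stood at 235 ± 59.1 against 53.8 ± 38.2 CPM. In the BMP list 7 of 13 rose (10 higher adjusted over the list alone, camera adjusted p = 2.5e-06, adjusted p = 0.086 with an estimated correlation). Among them the ligand BMP2 stood at 254 ± 25.6 against 6.72 ± 1.09 CPM. In the neuromesodermal and caudal list 10 of 15 rose (10 higher adjusted over the list alone, camera adjusted p = 8.1e-05, adjusted p = 0.21 with an estimated correlation). The caudal gene CDX2 stood at 11.1 ± 7.42 against 0.433 ± 0.431 CPM. CDX1 stood at 1.37 ± 0.503 against 0.852 ± 0.781 CPM (adjusted p = 0.31, edgeR). CDX1 gained the call without WNT3A 100 SOX2-positive replicate 1 (edgeR adjusted p = 0.045). In the presomitic and somitic list 6 of 11 rose (7 higher adjusted over the list alone, camera adjusted p = 0.00075, adjusted p = 0.19 with an estimated correlation). TBX6 stood at 13.1 ± 4.22 against 4.43 ± 0.846 CPM. MSGN1 had no count in the SOX2-positive libraries and 0.414 ± 0.425 CPM in the SOX2-negative ones (adjusted p = 0.1, or 0.038 with no filter on low counts, edgeR). In the endothelial and blood list 5 of 9 rose and 1 fell (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.027, adjusted p = 0.21 with an estimated correlation). That list lost its camera call without WNT3A 100 SOX2-negative replicate 1 or WNT3A 1000 SOX2-negative replicate 2 (adjusted p = 0.058 to 0.11). The gene that fell was KDR, named after its value was seen. At 100 ng/ml it stood at 20.02 and 22.4 CPM in SOX2-negative and 108 and 96.6 CPM in SOX2-positive replicates 1 and 2, and at 1000 ng/ml at 82.5 and 271 against 190.4 and 142 CPM, where replicate 2 was higher in the SOX2-negative cells. KDR lost the call without any 1 library other than the WNT3A 1000 SOX2-negative libraries (edgeR adjusted p = 0.055 to 0.1). The call also ended with only the compared groups fitted (adjusted p = 0.054, edgeR).

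Of the HOX genes, which mark position along the body axis, HOXB9 (ENSG00000170689, chromosome 17, 48621159 to 48626356) rose to 2.54 ± 3.70 from 0.0487 ± 0.0643 CPM (adjusted p = 0.01, edgeR). HOXB1 stood at 0.272 ± 0.388 against 0.407 ± 0.458 CPM (adjusted p = 0.33, edgeR). Of HOX groups 1 to 4, 3 of 6 measured genes rose, among them HOXB2 and HOXB3 (3 higher adjusted over the list alone, camera adjusted p = 0.0023, adjusted p = 0.21 with an estimated correlation). Of groups 5 to 9, 2 of 9 rose, HOXB6 and HOXB9 (2 higher adjusted over the list alone, camera adjusted p = 0.0034, adjusted p = 0.44 with an estimated correlation). HOXB2 lost the call without WNT3A 1000 SOX2-negative replicate 2 (edgeR adjusted p = 0.053). Groups 10 to 13 had 2 measured genes, 0 called by edgeR, 0 by DESeq2, 1 by limma-trend and 1 at an unadjusted p under 0.05 (1 higher adjusted over the list alone, camera adjusted p = 0.15). These groups gained a camera call without WNT3A 1000 SOX2-negative replicate 1 (adjusted p = 0.0037). In WNT3A 1000 SOX2-negative replicate 2 the mean log2 CPM of the 3 lists was 1.41, 0.86 and 0.40, against -2.38 to -0.23, -2.94 to -1.89 and -2.66 to -2.10 in the other SOX2-negative libraries. HOXB9 was at 8.07 CPM there and at 0.300 to 1.02 CPM in those others. Without this library the camera adjusted p of groups 1 to 4 and 5 to 9 was 0.0023 and 0.025, and no gene of groups 10 to 13 passed the filter on low counts.

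In the pluripotency list 12 of 15 genes fell (12 lower adjusted over the list alone, camera adjusted p = 1.1e-07, adjusted p = 0.086 with an estimated correlation). SOX2, the gene of the sort, is a member and is among those that fell. Its share of the count and of the camera test was set by the sort. PRDM14 stood at 1.58 ± 1.01 against 70.8 ± 14.2 CPM and NANOG at 7.82 ± 4.42 against 62.0 ± 40.2 CPM. POU5F1 has 4 identifiers that share reads. The one on the primary chromosome fell, from 127 ± 57.3 to 28.4 ± 14.4 CPM (adjusted p = 0.012, edgeR). Together they held 1276 ± 399 and 1604 ± 461 CPM in SOX2-positive cells at 100 and 1000 ng/ml against 598 ± 164 and 329 ± 158 CPM in SOX2-negative cells. In the forebrain list 4 of 11 fell, LHX5, RAX, FEZF1 and HESX1 (4 lower adjusted over the list alone, camera adjusted p = 0.04, adjusted p = 0.44 with an estimated correlation). The forebrain list lost its camera call without WNT3A 100 SOX2-positive replicate 2, WNT3A 1000 SOX2-positive replicate 2, WNT3A 100 SOX2-negative replicate 1 or WNT3A 1000 SOX2-negative replicate 2 (adjusted p = 0.058 to 0.13). OTX2, a forebrain and midbrain regulator, stood at 65.1 ± 30.0 against 73.5 ± 23.2 CPM (adjusted p = 0.76, edgeR). In the midbrain and hindbrain list 4 of 11 rose, PAX2, IRX3, IRX1 and LMX1B, and 1 fell, IRX2 (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.049, adjusted p = 0.21 with an estimated correlation). This list lost its camera call on leaving out either WNT3A 100 SOX2-negative library or WNT3A 1000 SOX2-negative replicate 1 (adjusted p = 0.073 to 0.12). LMX1B was named after its value was seen. In the neural progenitor list 2 of 13 rose and 5 fell (2 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.19). PAX6 fell from 2.12 ± 2.13 to 0.115 ± 0.0872 CPM. RAX lost the call on leaving out WNT3A 100 SOX2-positive replicate 2, WNT3A 1000 SOX2-positive replicate 2 or either WNT3A 1000 SOX2-negative library (edgeR adjusted p = 0.07 to 0.25), and PAX6 without any 1 library other than WNT3A 100 SOX2-positive replicate 1 and WNT3A 1000 SOX2-positive replicate 1 (adjusted p = 0.053 to 0.19). LMX1B lost the call without WNT3A 100 SOX2-positive replicate 1, WNT3A 1000 SOX2-positive replicate 1, WNT3A 100 SOX2-negative replicate 2 or WNT3A 1000 SOX2-negative replicate 1 (edgeR adjusted p = 0.095 to 0.13). With only the compared groups fitted, edgeR's adjusted p for RAX, PAX6 and LMX1B was 0.052, 0.054 and 0.07, and limma-trend's for PAX6 0.078. With 3 doses averaged edgeR gave RAX and PAX6 an adjusted p of 0.067 and 1.

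Further lists went both ways, the first of them neural crest (6 of 13 higher and 4 lower, 7 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.15). Surface ectoderm and amnion was another (5 of 11 higher and 4 lower, 5 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.4). So was the Nodal pathway (4 of 11 higher and 1 lower, 4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.14). SOX10, a neural crest regulator, stood at 7.33 ± 1.42 against 4.47 ± 0.532 CPM (adjusted p = 0.073, edgeR). SOX10 gained the call without WNT3A 100 SOX2-negative replicate 1 (edgeR adjusted p = 0.049). The keratin KRT8 rose from 389 ± 86.9 to 3721 ± 1819 CPM, whereas KRT7 fell. NODAL stood at 2.90 ± 2.58 against 5.40 ± 6.45 CPM and LEFTY1 at 2.37 ± 1.99 against 1.70 ± 2.67 CPM. Neither was called by edgeR (adjusted p = 0.67 and 0.56). LEFTY2, a Nodal target and antagonist, rose from 4.54 ± 6.39 to 16.1 ± 4.71 CPM. CER1 and SMAD7 also rose, and GDF3 fell. LEFTY2 lost the call on leaving out WNT3A 1000 SOX2-positive replicate 2, WNT3A 100 SOX2-negative replicate 2 or either WNT3A 1000 SOX2-negative library (edgeR adjusted p = 0.056 to 0.11), and CER1 without WNT3A 100 SOX2-positive replicate 2 (adjusted p = 0.071). DESeq2 gave LEFTY2 an adjusted p of 0.062, and edgeR with only the compared groups 0.061.

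In the retinoic acid list genes moved both ways (3 of 9 higher and 3 lower, 4 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.36). The Notch list also had calls in both directions (6 of 12 higher and 2 lower, 6 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.13). In the epithelial list (2 of 9 higher and 2 lower, 2 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.9) EPCAM and CRB3 rose and E-cadherin, CDH1, and ESRP1 fell. In the glycolysis and hypoxia list (2 of 16 higher and 3 lower, 2 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.76) VEGFA and SLC2A3 rose and HK2, PGK1 and PDK1 fell. PDK1 was named after its value was seen. The epithelial median log2 fold change was 0.03 and its mean -0.08. Those of the glycolysis list were -0.18 and 0.03. Camera ranked both lists down. ESRP1 lost the call without any 1 library other than the WNT3A 100 SOX2-negative libraries (edgeR adjusted p = 0.069 to 0.12), and PGK1 without WNT3A 100 SOX2-positive replicate 2, WNT3A 1000 SOX2-positive replicate 2 or WNT3A 1000 SOX2-negative replicate 1 (adjusted p = 0.056 to 0.072). PDK1 lost the call without any 1 library other than WNT3A 100 SOX2-negative replicate 1 and WNT3A 1000 SOX2-negative replicate 2 (edgeR adjusted p = 0.057 to 0.11). With only the compared groups fitted edgeR gave ESRP1 and PDK1 an adjusted p of 0.058 and 0.059. With 3 doses averaged it gave ESRP1 an adjusted p of 0.056. The cell cycle list of 13 genes had 0 called by edgeR, 0 by DESeq2, 0 by limma-trend and 0 at an unadjusted p under 0.05 (0 adjusted over the list alone, camera adjusted p = 0.3). The dissociation stress list of 10 had 0 called by edgeR, 0 by DESeq2, 0 by limma-trend and 1 at an unadjusted p under 0.05 (0 adjusted over the list alone, camera adjusted p = 0.27). The 13 mitochondrially encoded genes had 0 called by edgeR, 2 by DESeq2, 0 by limma-trend and 3 at an unadjusted p under 0.05 (0 adjusted over the list alone, camera adjusted p = 0.047, adjusted p = 0.55 with an estimated correlation). Their list lost its camera call without any 1 library other than WNT3A 100 SOX2-positive replicate 1 and WNT3A 100 SOX2-negative replicate 1 and WNT3A 1000 SOX2-negative replicate 1 (adjusted p = 0.052 to 0.15).

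**Figure D2:**
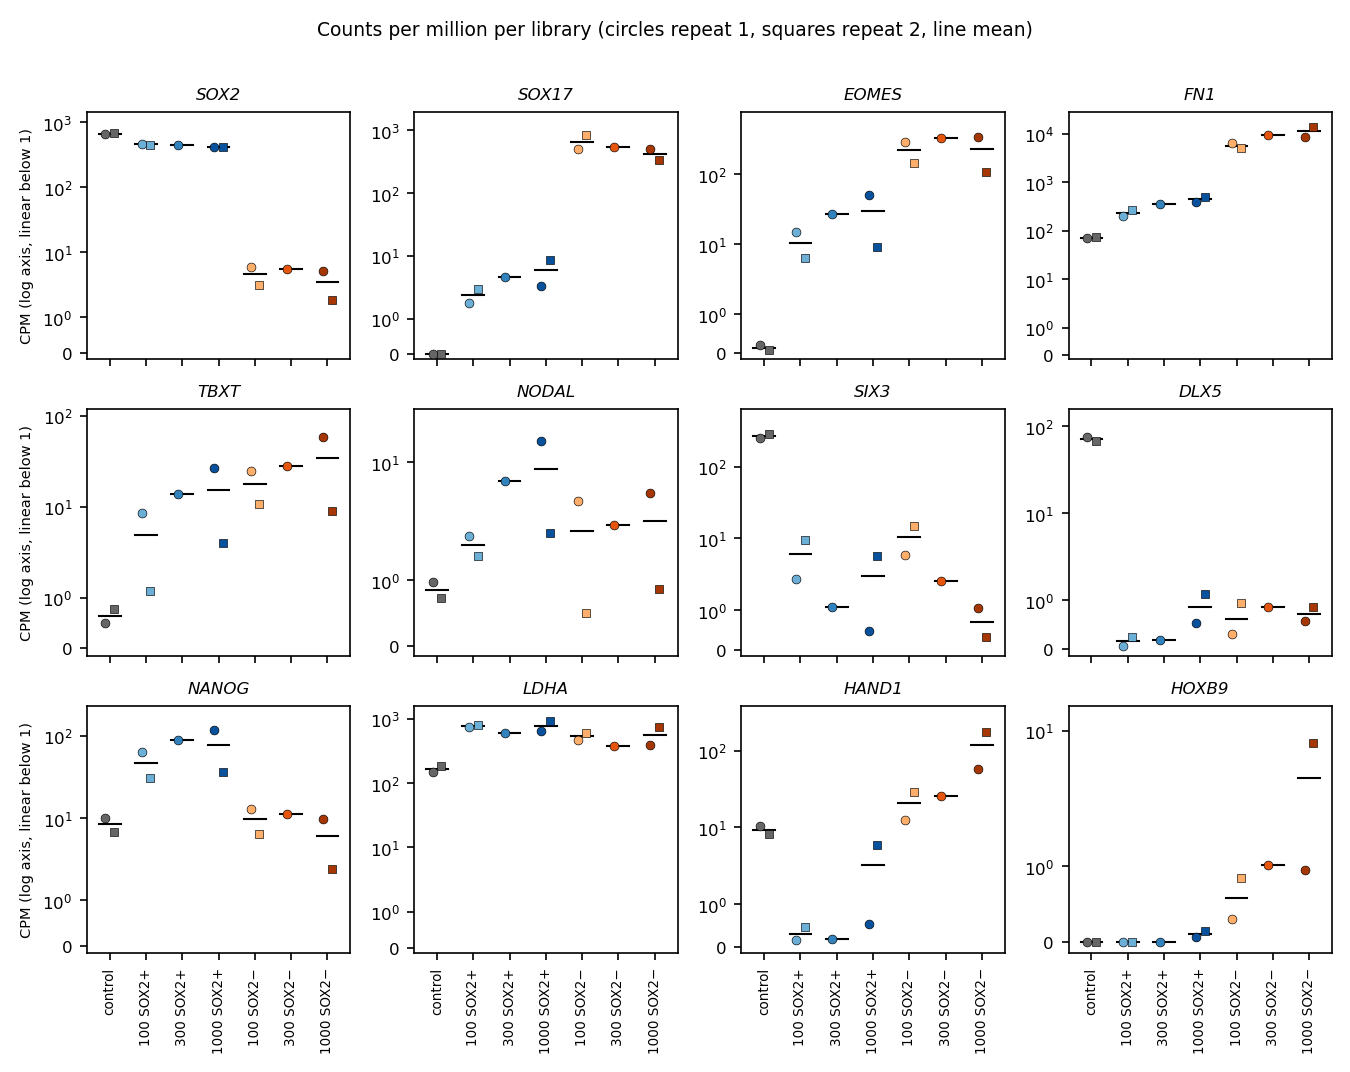
CPM of 12 genes per library (vertical log axis, linear below 1) for the 7 groups, with circles for repeat 1, squares for repeat 2 and a line at the group mean (at 300 ng/ml, the single library). SOX2 is at 4.59 CPM or below in the means of the SOX2-negative groups at 100 and 1000 ng/ml, and SOX17 at 421 CPM or above.

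The second question was how cells that stayed SOX2-positive under FGF8 and WNT3A differed from control. DLX5 (ENSG00000105880, chromosome 7, 97020392 to 97024950), a homeobox gene of the preplacodal ectoderm, fell from 71.6 ± 5.15 to 0.149 ± 0.141 CPM at 100 ng/ml and 0.853 ± 0.455 CPM at 1000 ng/ml by edgeR. Its log2 fold change was -8.79 ± 0.71 and -6.35 ± 0.60 (SE, adjusted p = 0.0011 and 0.0017, edgeR). SIX3, an anterior forebrain regulator, fell from 270.4 ± 29.5 to 6.04 ± 4.75 and 3.04 ± 3.63 CPM (adjusted p = 0.018 and 0.01, edgeR). TDGF1, the Nodal co-receptor, rose from 17.9 ± 4.86 to 374 ± 33.6 and 399 ± 16.2 CPM. EOMES rose from 0.139 ± 0.0922 to 10.5 ± 5.90 and 29.2 ± 28.4 CPM. The lactate dehydrogenase LDHA rose from 166 ± 25.4 to 773 ± 31.5 and 773 ± 188 CPM. For these 3 genes the adjusted p was at most 0.029 by edgeR. SIX3, EOMES and LDHA lost the call at 100 ng/ml without any 1 of the 4 libraries (edgeR adjusted p = 0.055 to 0.28). They lost the call at 1000 ng/ml on leaving out either control library (edgeR adjusted p = 0.053 to 0.14). The labels do not say whether control cells passed through a gate, so these folds, and those of SOX2-negative cells against control, can hold effects of the sort. The dissociation stress list had a mean log2 CPM of 5.17 and 4.38 in control, 6.08 and 5.03 at 100 ng/ml and 6.18 and 5.87 at 1000 ng/ml. Its mean log2 fold change was 0.65 and 0.99 (0 adjusted over the list alone, camera adjusted p = 0.77 and 0.22). Of its 10 genes edgeR, DESeq2 and limma-trend called 0 at either dose, with 0 and 2 at an unadjusted p under 0.05 by edgeR.

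At 100 ng/ml 558 genes were called by edgeR (355 higher, 203 lower). The highest rises included CST1 (36.3 ± 19.0 against 0.0948 ± 0.0821 CPM), FOXD3 (34.0 ± 8.39 against 0.598 ± 0.379 CPM) and the mitochondrial adenylate kinase AK4 (135 ± 34.9 against 4.12 ± 0.502 CPM). The neurotensin precursor NTS and SYT4 were among them. The deepest falls included GRHL3, an epidermal regulator (1.48 ± 0.195 against 80.6 ± 7.11 CPM), DLX3 and DLX6. At 1000 ng/ml 734 genes were called (477 higher, 257 lower). SOX17 had no count in the control libraries and was at least 97.6-fold higher (5.91 ± 3.60 CPM). LEFTY2 rose from 0.0876 ± 0.0201 to 8.26 ± 8.10 CPM. CST1 and NTS lost the call at 100 ng/ml without control replicate 2 (edgeR adjusted p = 0.055 to 0.059), and DLX6 without any 1 of the 4 libraries (adjusted p = 0.088 to 0.17). SOX17 lost the call at 1000 ng/ml without control replicate 2 (edgeR adjusted p = 0.054), and LEFTY2 on leaving out either control library or SOX2-positive replicate 1 (adjusted p = 0.22 to 0.34). At 100 ng/ml the count of called genes was 91 without control replicate 1, 39 without control replicate 2, 83 without SOX2-positive replicate 1 and 107 without SOX2-positive replicate 2. It was 101 without control replicate 1, 60 without control replicate 2, 188 without SOX2-positive replicate 1 and 404 without SOX2-positive replicate 2 at 1000 ng/ml. An edgeR fit to the compared groups alone called 2183 and 1673 genes, and DESeq2 1344 and 1603.

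Of 27 lists, 12 had a camera call at 100 ng/ml and 10 at 1000 ng/ml. With an estimated correlation 0 kept it. In the forebrain list 2 of 11 genes fell at 100 ng/ml, SIX3 and FEZF1. At 1000 ng/ml 5 fell, among them LHX2 and OTX2 (8 and 11 lower adjusted over the list alone, camera adjusted p = 1.2e-08 and 4.4e-10, adjusted p = 0.24 and 0.32 with an estimated correlation). OTX2 stood at 351 ± 6.24 CPM in control, 88.8 ± 17.8 CPM at 100 ng/ml (adjusted p = 0.067) and 58.2 ± 19.0 CPM at 1000 ng/ml (adjusted p = 0.022, edgeR). DESeq2 called it at 100 ng/ml (adjusted p = 5e-04), as did edgeR with only the compared groups (0.00077) or with identifiers summed (0.041). PAX6 stood at 16.2 ± 12.3, 2.05 ± 2.55 and 2.18 ± 2.67 CPM (adjusted p = 0.33 and 0.32, edgeR). OTX2 at 100 ng/ml and PAX6 at both doses passed edgeR's test with no filter on low counts (adjusted p at most 0.00017). In the surface ectoderm and amnion list 5 and 4 of 11 fell (6 and 6 lower adjusted over the list alone, camera adjusted p = 4.1e-05 and 0.00084, adjusted p = 0.24 and 0.32 with an estimated correlation). These were DLX5, GATA3 and TFAP2A at both doses, with ISL1 and TFAP2C at 100 ng/ml and IGFBP3 at 1000 ng/ml. TFAP2C was named after its value was seen. GATA3 stood at 71.1 ± 16.6 CPM in control against 3.19 ± 0.934 and 8.50 ± 4.09 CPM. In the retinoic acid list 1 of 9 fell at either dose, the synthesis enzyme ALDH1A2 (1 and 1 higher, 5 and 4 lower adjusted over the list alone, camera adjusted p = 0.008 and 0.005, adjusted p = 0.33 and 0.41 with an estimated correlation). ALDH1A2 stood at 57.5 ± 14.4 CPM in control against 1.64 ± 1.55 and 2.04 ± 2.30 CPM. In the BMP list at 100 ng/ml BMP4, BMP7 and SMAD6 fell and CHRD rose (1 of 13 higher and 3 lower, 1 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.0058, adjusted p = 0.33 with an estimated correlation). BMP4 stood at 57.7 ± 6.49 CPM in control and 3.76 ± 0.191 CPM. The BMP list lost its camera call at that dose without SOX2-positive replicate 2 (adjusted p = 0.058). The BMP list had no camera call at 1000 ng/ml (1 of 13 higher and 3 lower, 3 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.18). FEZF1, TFAP2A, TFAP2C, ALDH1A2, BMP7 and SMAD6 lost the call at 100 ng/ml without any 1 of the 4 libraries (edgeR adjusted p = 0.061 to 0.25), and ISL1 on leaving out either control library or SOX2-positive replicate 2 (adjusted p = 0.059 to 0.072). CHRD lost the call at 100 ng/ml on leaving out either control library or SOX2-positive replicate 1 (edgeR adjusted p = 0.12 to 0.2). FEZF1 lost the call at 1000 ng/ml without control replicate 2 (edgeR adjusted p = 0.074), and LHX2 and OTX2 without any 1 of the 4 libraries (adjusted p = 0.069 to 0.36). TFAP2A, IGFBP3 and ALDH1A2 lost the call at 1000 ng/ml on leaving out either control library or SOX2-positive replicate 1 (edgeR adjusted p = 0.097 to 0.21).

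In the glycolysis and hypoxia list 5 and 6 of 16 genes rose at 100 and 1000 ng/ml (11 and 9 higher adjusted over the list alone, camera adjusted p = 1.8e-08 and 4.7e-08, adjusted p = 0.24 and 0.32 with an estimated correlation). Those at 100 ng/ml were PDK1, LDHA, BNIP3, PGK1 and SLC2A3, the last named after its value was seen. PDK1, a kinase that inhibits pyruvate dehydrogenase, rose from 12.4 ± 0.0144 to 75.5 ± 4.68 and 86.1 ± 6.48 CPM. BNIP3 rose from 39.6 ± 2.92 to 165 ± 6.14 and 162 ± 31.4 CPM. In the same libraries mitochondrially encoded transcripts took 4.7 to 5.63% of the counts, against 4.22 and 2.79% in control. Their list had a median log2 fold change of 0.48 and 0.34 at 100 and 1000 ng/ml, with 0 called by edgeR, 0 by DESeq2, 0 by limma-trend and 3 at an unadjusted p under 0.05 at 100 ng/ml (0 adjusted over the list alone, camera adjusted p = 0.013 and 0.069, adjusted p = 0.54 and 0.79 with an estimated correlation). It lost its camera call at 100 ng/ml without control replicate 2 or SOX2-positive replicate 2 (adjusted p = 0.1 to 0.61). With the repeat as a block the camera adjusted p at 1000 ng/ml was 0.039, and without control replicate 1 it was 0.00047. In the primitive streak list 4 of 11 rose at 100 ng/ml, EOMES, FOXA2, EVX1 and APLNR. At 1000 ng/ml 5 rose, with GATA6 besides (5 and 8 higher, 0 and 1 lower adjusted over the list alone, camera adjusted p = 1.7e-05 and 4.3e-06, adjusted p = 0.33 and 0.32 with an estimated correlation). APLNR at 1000 ng/ml was named after its value was seen. Other genes abundant in SOX2-negative cells and low in control were above control in these libraries by a median of 3.96 and 2.38% of their SOX2-negative rise at 100 ng/ml, and of 11.6 and 3.55% at 1000 ng/ml (replicates 1 and 2). TBXT stood at 0.640 ± 0.185, 4.85 ± 5.15 and 15.3 ± 15.9 CPM in control and at the doses in turn, and was not called by edgeR with the filter on low counts. MIXL1, also not called, stood at 0.237 ± 0.0243, 3.42 ± 3.66 and 10.3 ± 12.1 CPM. With the repeat as a block MIXL1 passed edgeR's test at both doses (adjusted p = 0.022 and 0.0048) and TBXT at 1000 ng/ml (adjusted p = 0.03). With no filter both passed it at both doses (adjusted p at most 3.9e-10, edgeR). With only the compared groups MIXL1 passed at both (0.045 and 0.038) and TBXT at 1000 ng/ml (0.031). DESeq2 called MIXL1 and TBXT at 1000 ng/ml (adjusted p = 0.0078 and 0.0086). In the pluripotency list 1 of 15 rose at 100 ng/ml, TDGF1. At 1000 ng/ml 3 rose, with GDF3 and NANOG besides, while LIN28A fell at both (6 and 5 higher, 1 and 1 lower adjusted over the list alone, camera adjusted p = 0.0091 and 0.029, adjusted p = 0.33 and 0.41 with an estimated correlation). That list lost its camera call at 1000 ng/ml without control replicate 2 or SOX2-positive replicate 1 (adjusted p = 0.056 to 0.074). NANOG stood at 8.38 ± 2.35 CPM in control, 46.6 ± 22.7 CPM at 100 ng/ml (adjusted p = 0.11, or 0.011 with the repeat as a block, 8e-14 with no filter, 0.0053 with only the compared groups and 0.0032 by DESeq2) and 77.5 ± 58.1 CPM at 1000 ng/ml (adjusted p = 0.046, edgeR). Of the FGF targets 3 and 5 of 12 rose and 1 fell at each dose, the phosphatase DUSP4 (8 and 8 higher, 1 and 1 lower adjusted over the list alone, camera adjusted p = 0.0023 and 0.00027, adjusted p = 0.5 and 0.41 with an estimated correlation). DUSP6 rose from 3.69 ± 0.178 to 48.6 ± 30.4 and 59.0 ± 57.9 CPM. SPRY4 and SPRY2 rose at 100 ng/ml. Of the WNT targets, AXIN2 stood at 28.7 ± 1.25, 44.9 ± 4.84 and 40.3 ± 7.67 CPM. SP5 stood at 8.72 ± 7.50, 15.5 ± 9.62 and 32.3 ± 23.1 CPM, and edgeR with the filter, fitted to all groups, called neither gene at either dose. It called AXIN2 at 100 ng/ml with only the compared groups (adjusted p = 0.03) and SP5 at both doses with no filter (adjusted p at most 0.036). PGK1, SLC2A3, EVX1, LIN28A, DUSP6, SPRY4 and SPRY2 lost the call at 100 ng/ml without any 1 of the 4 libraries (edgeR adjusted p = 0.053 to 0.27), and PDK1 without control replicate 2 (adjusted p = 0.052). BNIP3 and APLNR lost the call at 100 ng/ml on leaving out either control library (edgeR adjusted p = 0.066 to 0.081), and FOXA2 without control replicate 2 or SOX2-positive replicate 1 (adjusted p = 0.056 to 0.13). BNIP3 and EVX1 lost the call at 1000 ng/ml on leaving out either control library (edgeR adjusted p = 0.062 to 0.1), and FOXA2 without control replicate 2 (adjusted p = 0.073). GATA6, NANOG and DUSP6 lost the call at 1000 ng/ml on leaving out either control library or SOX2-positive replicate 1 (edgeR adjusted p = 0.071 to 0.34), and GDF3 and LIN28A without any 1 of the 4 libraries (adjusted p = 0.055 to 0.32). DUSP4 lost the call at 1000 ng/ml without control replicate 2 or SOX2-positive replicate 1 (edgeR adjusted p = 0.064 to 0.081).

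**Figure D3:**
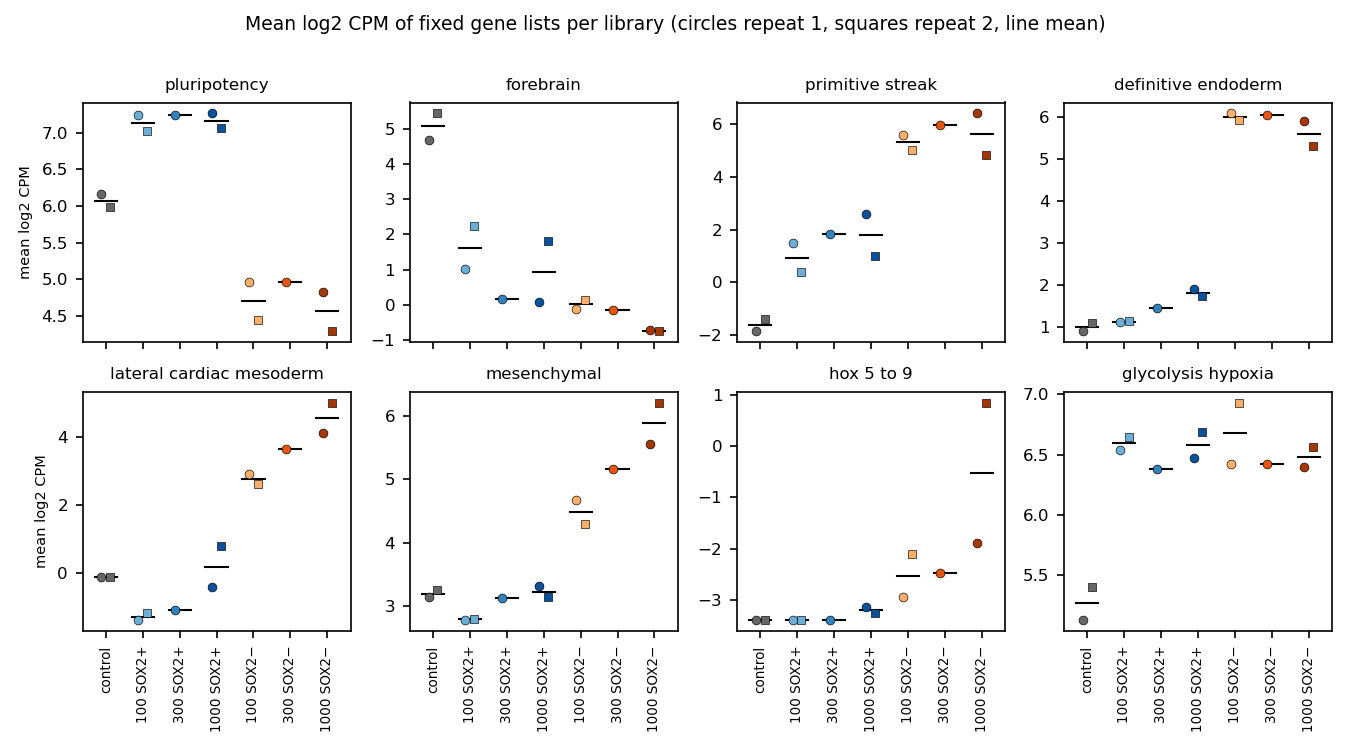
Mean log2 CPM of 8 gene lists per library (vertical axis) for the 7 groups, with circles for repeat 1, squares for repeat 2 and a line at the group mean (at 300 ng/ml, the single library). The forebrain list is at 4.69 and 5.43 in the controls and between -0.74 and 2.24 in the other libraries.

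The SOX2-negative cells were set against the same controls. SOX17, with no count in the control libraries, was at least 10726-fold higher at 100 ng/ml (659 ± 235 CPM) and at least 6417-fold higher at 1000 ng/ml (421 ± 114 CPM). FOXA2, another endoderm regulator, rose from 0.0764 ± 0.108 to 244 ± 36.0 and 147 ± 28.8 CPM. EOMES rose from 0.139 ± 0.0922 to 217 ± 103 and 224 ± 165 CPM, and the streak gene MIXL1 from 0.237 ± 0.0243 to 26.0 ± 27.1 and 61.4 ± 64.9 CPM. TBXT rose from 0.640 ± 0.185 to 17.8 ± 10.0 and 34.1 ± 35.4 CPM (adjusted p = 0.037 and 0.02, edgeR). The forebrain gene FEZF1 fell from 530.1 ± 110.1 to 2.28 ± 0.267 and 0.842 ± 0.0839 CPM. By edgeR 3046 genes were called at 100 ng/ml (1748 higher, 1298 lower) and 2752 at 1000 ng/ml (1651 higher, 1101 lower). CST1, the transcription factor RUNX1, MOBP and GPR55 were among the highest rises at both doses. The last 3 had no count in control and stood at 44.2 ± 31.5, 57.9 ± 9.20 and 18.2 ± 2.48 CPM at 100 ng/ml. CDH9 and HMX2, at 14.5 ± 1.98 and 6.23 ± 0.381 CPM in control, had no count in SOX2-negative libraries at either dose (at least 192-fold and at least 84.1-fold lower at 100 ng/ml). Other genes with an identifier among the most changed have several identifiers that share reads, and are given summed over them. The endoderm and heart regulator GATA4 rose from 0.0734 ± 0.104 to 129.7 ± 26.6 and 198 ± 51.2 CPM (adjusted p = 5.9e-06 and 3.7e-06, edgeR). DOC2B and PRSS2 rose too (adjusted p = 0.00098 and 7.9e-05 at 100 ng/ml, 0.0013 and 0.00024 at 1000 ng/ml, edgeR). TAP2, a subunit of the antigen peptide transporter, fell from 11.2 ± 1.94 to 3.54 ± 2.22 and 3.98 ± 1.95 CPM (adjusted p = 0.028 and 0.041, edgeR). TAP2 summed lost edgeR's call at 100 ng/ml on leaving out either control library (adjusted p = 0.073 to 0.14) and at 1000 ng/ml on leaving out either control library or SOX2-negative replicate 2 (adjusted p = 0.1 to 0.24). Summed, KIAA1147, TRIM27 and BAG6 were not called by edgeR (adjusted p = 0.058, 0.64 and 0.94 at 100 ng/ml, 0.52, 0.19 and 0.6 at 1000 ng/ml). At 100 ng/ml KIAA1147 was called lower on leaving out SOX2-negative replicate 1 (adjusted p = 0.00062). MIXL1 lost the call at 100 ng/ml on leaving out either control library or SOX2-negative replicate 1 (edgeR adjusted p = 0.067 to 0.18), and TBXT without any 1 of the 4 libraries (adjusted p = 0.051 to 0.19). MIXL1 and TBXT lost the call at 1000 ng/ml on leaving out either control library or SOX2-negative replicate 1 (edgeR adjusted p = 0.066 to 0.14). At 100 ng/ml the count of called genes was 1213 without control replicate 1, 1142 without control replicate 2 and 6649 without SOX2-negative replicate 1. It was 1332 without control replicate 1, 1155 without control replicate 2, 1827 without SOX2-negative replicate 1 and 1643 without SOX2-negative replicate 2 at 1000 ng/ml. A fit to the compared groups alone called 1509 at 100 ng/ml. DESeq2 did not call HMX2 (adjusted p = 0.095 and 0.11).

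Of 27 lists, 12 had a camera call at 100 ng/ml and 17 at 1000 ng/ml. With an estimated correlation 0 kept it. In the primitive streak list 9 of 11 genes rose at either dose (9 and 10 higher adjusted over the list alone, camera adjusted p = 3.4e-08 and 8e-09, adjusted p = 0.27 and 0.13 with an estimated correlation). In the definitive endoderm list 8 of 11 rose at either dose (10 and 9 higher, 1 and 2 lower adjusted over the list alone, camera adjusted p = 8.9e-07 and 2.2e-05, adjusted p = 0.068 and 0.13 with an estimated correlation). In that list 1 gene fell at each dose, SHISA2, named after its value was seen. Of the FGF targets 10 and 11 of 12 rose (11 and 11 higher, 1 and 0 lower adjusted over the list alone, camera adjusted p = 1.5e-05 and 2.8e-07, adjusted p = 0.27 and 0.18 with an estimated correlation). DUSP6 stood at 188 ± 20.2 and 282 ± 35.5 against 3.69 ± 0.178 CPM. Of the WNT targets 7 and 6 of 12 rose (7 and 8 higher adjusted over the list alone, camera adjusted p = 0.00023 and 2.5e-05, adjusted p = 0.26 and 0.13 with an estimated correlation). SP5 stood at 411 ± 74.9 and 225 ± 97.8 against 8.72 ± 7.50 CPM. In the mesenchymal list 6 and 11 of 13 rose (6 and 11 higher, 1 and 0 lower adjusted over the list alone, camera adjusted p = 0.0077 and 2.7e-07, adjusted p = 0.27 and 0.13 with an estimated correlation). This list lost its camera call at 100 ng/ml without SOX2-negative replicate 1 (adjusted p = 0.087). In the forebrain list 9 and 8 of 11 fell (10 and 11 lower adjusted over the list alone, camera adjusted p = 8.1e-07 and 2.3e-08, adjusted p = 0.27 and 0.13 with an estimated correlation). In the lateral and cardiac mesoderm list 7 and 9 of 11 rose (7 and 10 higher, 1 and 0 lower adjusted over the list alone, camera adjusted p = 0.0023 and 2.7e-07, adjusted p = 0.27 and 0.13 with an estimated correlation). The dissociation stress list had 0 called by edgeR, 2 by DESeq2, 0 by limma-trend and 4 at an unadjusted p under 0.05 at 100 ng/ml. At 1000 ng/ml 3 of 10 rose, the immediate early genes JUN, JUNB and EGR1 (0 and 5 higher, 0 and 1 lower adjusted over the list alone, camera adjusted p = 0.26 and 0.084). With the repeat as a block the camera adjusted p at 1000 ng/ml was 0.03, and without WNT3A 1000 SOX2-negative replicate 2 it was 0.032. SHISA2 lost the call at 100 ng/ml on leaving out either control library or SOX2-negative replicate 1 (edgeR adjusted p = 0.084 to 0.16). JUN and JUNB lost the call at 1000 ng/ml on leaving out either control library or SOX2-negative replicate 1 (edgeR adjusted p = 0.088 to 0.21), and EGR1 on leaving out control replicate 2 or either SOX2-negative library (adjusted p = 0.11 to 0.24).

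The third question was whether the dose of WNT3A mattered, 1000 against 100 ng/ml within a gate. In SOX2-positive cells NODAL (ENSG00000156574, chromosome 10, 70432315 to 70447951) stood at 2.00 ± 0.543 and 8.79 ± 8.85 CPM (adjusted p = 1, edgeR). EOMES stood at 10.5 ± 5.90 and 29.2 ± 28.4 CPM (adjusted p = 1) and the mesoderm gene HAND1 at 0.302 ± 0.217 and 3.20 ± 3.78 CPM (adjusted p = 1), neither past edgeR's test. HAND1 stood at 9.31 ± 1.53 CPM in control. With no filter, a fit not relied on, edgeR called EOMES, HAND1 and GDF3 for dose (adjusted p at most 0.00014). OTX2, NANOG and, named after their values were seen, GATA6 and GDF3 had been called against control at 1000 ng/ml. They were not called between the doses (adjusted p = 1 for each, edgeR). EdgeR called 1 of 17706 genes, 1 of the 4 identifiers of ATF6B, which share reads. It had no count at 100 ng/ml and 10.3 ± 0.586 CPM at 1000 ng/ml, while ATF6B summed over its identifiers stood at 39.0 ± 5.77 CPM and 37.3 ± 1.54 CPM. By edgeR 320 genes had an unadjusted p under 0.05, where chance alone gives 885. DESeq2 called 18 genes and limma-trend 3. The 11 genes of the lateral and cardiac mesoderm list had 0 called by edgeR, 1 by DESeq2, 0 by limma-trend and 6 at an unadjusted p under 0.05. As a set they were higher at 1000 ng/ml (4 higher adjusted over the list alone, camera adjusted p = 1.7e-09, adjusted p = 0.18 with an estimated correlation). Against control 3 of them fell at 100 ng/ml, and at 1000 ng/ml 1 rose and 1 fell (1 and 5 higher, 4 and 3 lower adjusted over the list alone, camera adjusted p = 0.019 and 0.94, adjusted p = 0.5 and 0.96 with an estimated correlation). The mean log2 CPM of the list was -0.11 and -0.11 in control, -1.39 and -1.19 at 100 ng/ml and -0.42 and 0.79 at 1000 ng/ml. It lost its camera call against control at 100 ng/ml without SOX2-positive replicate 1 (adjusted p = 0.06). The 11 of the Nodal pathway list had 0 called by edgeR, 0 by DESeq2, 0 by limma-trend and 3 at an unadjusted p under 0.05. They too were higher as a set (1 higher adjusted over the list alone, camera adjusted p = 0.00078, adjusted p = 0.26 with an estimated correlation). The Nodal list lost its camera call without WNT3A 1000 replicate 1 (adjusted p = 0.16). The dissociation stress list, with 0 called by edgeR, 0 by DESeq2, 0 by limma-trend and 0 at an unadjusted p under 0.05, was also higher as a set (0 adjusted over the list alone, camera adjusted p = 0.041, adjusted p = 0.43 with an estimated correlation). It lost its camera call on leaving out WNT3A 100 replicate 2 or either WNT3A 1000 library (adjusted p = 0.07 to 0.89). The other genes abundant in SOX2-negative cells stood above control by a median of 3.96 and 11.6% of their SOX2-negative rise at 100 and 1000 ng/ml in replicate 1, and of 2.38 and 3.55% in replicate 2. A camera call was made for 14 of 27 lists, and 0 kept it with an estimated correlation. The count of called genes was 0 without either WNT3A 100 library and 2 without WNT3A 1000 replicate 2.

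In SOX2-negative cells HAND1 stood at 20.6 ± 11.3 CPM at 100 ng/ml and 118 ± 83.4 CPM at 1000 ng/ml (adjusted p = 0.3, edgeR). CDX2 stood at 4.66 ± 0.583 and 17.5 ± 0.708 CPM (adjusted p = 0.3) and SOX17 at 659 ± 235 and 421 ± 114 CPM (adjusted p = 0.41), neither called by edgeR. With no filter it called HAND1 and CDX2 (adjusted p at most 0.013). HOXB9 was at 0.950 and 8.07 CPM in the replicates at 1000 ng/ml and at 0.300 and 0.850 CPM at 100 ng/ml (adjusted p = 0.3, edgeR). By edgeR 0 genes were called, while DESeq2 called 331, limma-trend 1, and 2920 had an unadjusted p under 0.05 (885 by chance). HOX groups 1 to 4 held 6 measured genes, 0 called by edgeR, 0 by DESeq2, 0 by limma-trend and 4 at an unadjusted p under 0.05. As a set these were higher at 1000 ng/ml (3 higher adjusted over the list alone, camera adjusted p = 8.4e-06, adjusted p = 0.26 with an estimated correlation). Without replicate 2 at 1000 ng/ml the camera adjusted p was 1e-06. The mesenchymal list of 13 had 0 called by edgeR, 6 by DESeq2, 0 by limma-trend and 7 at an unadjusted p under 0.05. It was higher as a set (7 higher adjusted over the list alone, camera adjusted p = 2.3e-05, adjusted p = 0.26 with an estimated correlation). The epithelial list of 9 had 0 called by edgeR, 1 by DESeq2, 0 by limma-trend and 3 at an unadjusted p under 0.05. That list was lower as a set (3 lower adjusted over the list alone, camera adjusted p = 0.002, adjusted p = 0.26 with an estimated correlation). Of 27 lists 5 had a camera call, and 0 kept it with an estimated correlation. The count of called genes was 5327 without WNT3A 100 replicate 1, 1 without WNT3A 100 replicate 2 and 3 without WNT3A 1000 replicate 1.

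Whether dose acted differently in the gates was tested as an interaction. SOX17 stood at 659 ± 235 and 421 ± 114 CPM at 100 and 1000 ng/ml in the SOX2-negative and at 2.41 ± 0.875 and 5.91 ± 3.60 CPM in the SOX2-positive cells (adjusted p = 0.56, edgeR). With no filter edgeR called it (adjusted p = 0.00016). SOX17 gained the call without WNT3A 100 SOX2-negative replicate 1 (edgeR adjusted p = 0.047). The definitive endoderm list of 11 genes had 0 called by edgeR, 1 by DESeq2, 0 by limma-trend and 5 at an unadjusted p under 0.05. It was lower as a set in this difference (2 lower adjusted over the list alone, camera adjusted p = 0.0029, adjusted p = 0.31 with an estimated correlation). Its mean log2 CPM was 5.30 in WNT3A 1000 SOX2-negative replicate 2 and 5.89 to 6.08 in the other SOX2-negative libraries, and without replicate 2 the camera adjusted p was 0.022. The list lost its camera call without WNT3A 100 SOX2-negative replicate 1 (adjusted p = 0.22). Only 1 gene passed edgeR's test, the same identifier of ATF6B, with 1204 genes at an unadjusted p under 0.05. With the repeat as a block edgeR called 0 genes, with 1094 at an unadjusted p under 0.05. DESeq2 called 25 and limma-trend 1. The count of called genes was 0 without either WNT3A 100 SOX2-positive library, WNT3A 1000 SOX2-positive replicate 1 or WNT3A 1000 SOX2-negative replicate 2, 3290 without WNT3A 100 SOX2-negative replicate 1 and 3 without WNT3A 1000 SOX2-negative replicate 1.

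At 300 ng/ml there was 1 library per gate, so nothing was tested. The SOX2-positive library had SOX2 at 455, EOMES at 26.8, NODAL at 6.93 and TBXT at 13.9 CPM. The SOX2-negative one had SOX17 at 531 and EOMES at 321 CPM. In repeat 1 the list mean at 300 ng/ml lay between those at 100 and 1000 ng/ml for 15 of 27 lists in SOX2-positive and 20 in SOX2-negative cells (33.3% by arbitrary order). Over genes, the change from 100 to 300 ng/ml correlated (Pearson) at 0.08 and 0.288 with that to 1000 ng/ml in repeat 2. The latter gave 0.153 and 0.21 between repeats. The planned share of dose-called genes (1 identifier) is not given.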

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

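The tests of GC content and length, of SOX2-positive cells in the SOX2-negative gate, of shared reads, of the gene lists in the dose difference between gates and of lists with a library left out were chosen only after the results they concern were seen. A library lay apart from the other libraries of its gate, past Dixon's 95% limit, in 7 of 68 measures, each over 5 libraries, where chance gives about 1 in 20.

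WNT3A 100 SOX2-negative replicate 2 had a TMM factor of 0.902 (the other SOX2-negative libraries 0.989 to 1.016), and lay at 58 on the second principal component (-18.6 to 0.4) and 99.8 on the third (-49.7 to -8). Leaving it out changed the counts of called genes less than leaving out replicate 1 of its group, which raised them all. SOX2-positive cells carried over in the sort are argued against, since 14 genes with at least 20 CPM in SOX2-positive libraries, and under 5% of that level in the other SOX2-negative libraries above 100 ng/ml, stood at a median of 1.69% of their SOX2-positive level, below the 3.77% in replicate 1. GC content and transcript length explained 40.5% of the variance of its log2 ratio to replicate 1. Removing both trends took the SD of the ratio from 0.76 to 0.58, above the 0.43 of the next pair. In the WNT3A 1000 SOX2-negative pair they explained 28.2%, with an opposite GC trend (r = -0.52 against 0.62), and in other pairs 0.4 to 5.8%. Dose in this gate was tested without correcting them. Such a bias may account for part of the distance. With 1 library the rest cannot be told from a difference of the biological repeat, for which no explanation was tested.

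EdgeR's only call for dose in SOX2-positive cells, and for the difference of the dose effect between the gates, was 1 of the 4 identifiers of ATF6B (DESeq2 called 18 and 25, limma-trend 3 and 1). Its dose effect in SOX2-negative cells minus that in SOX2-positive cells was -9.86 on the log2 scale as fitted on libraries with no count, which is no bound. Summed, ATF6B had a log2 fold change of -0.06 ± 0.21 SE for dose (adjusted p = 1, edgeR), and of -0.14 ± 0.30 in the dose difference between gates (adjusted p = 0.85). A division of reads among copies of the locus is consistent with these values, and no biological explanation was tested.

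In WNT3A 1000 SOX2-negative replicate 2 the mean log2 CPM of HOX groups 5 to 9 was 0.858 (the other SOX2-negative libraries -2.943 to -1.892), that of groups 10 to 13 0.396 (-2.658 to -2.103) and that of the definitive endoderm list 5.296 (5.894 to 6.081). In WNT3A 100 SOX2-positive replicate 2 the dissociation stress list stood at 5.034, against 5.873 to 6.176 in the other SOX2-positive libraries. The effect of dose differed between the gates by camera with its preset correlation for HOX groups 1 to 4 (adjusted p = 0.00079), HOX groups 5 to 9 (adjusted p = 0.0067) and the mesenchymal list (median log2 difference 1.04, adjusted p = 0.031), all higher in SOX2-negative cells. It was lower there for the definitive endoderm (-1.48, adjusted p = 0.0029) and epithelial lists (-0.40, adjusted p = 0.049) by the same camera test. HOX sizes are left out, as SOX2-positive counts were few or none. With an estimated correlation the 5 camera adjusted p were 0.66, 0.73, 0.73, 0.31 and 0.68, in the same order. The list of HOX groups 1 to 4 lost its camera call without WNT3A 100 SOX2-negative replicate 1 (adjusted p = 0.22). That of groups 5 to 9 lost its camera call without WNT3A 100 SOX2-negative replicate 1 or WNT3A 1000 SOX2-negative replicate 2 (adjusted p = 0.36 to 0.99). Definitive endoderm lost its camera call without WNT3A 100 SOX2-negative replicate 1 (adjusted p = 0.22). The mesenchymal list lost its camera call on leaving out WNT3A 1000 SOX2-positive replicate 2, either WNT3A 100 SOX2-negative library or WNT3A 1000 SOX2-negative replicate 2 (adjusted p = 0.055 to 0.26). The epithelial list lost its camera call without any 1 library other than WNT3A 1000 SOX2-negative replicate 2 (adjusted p = 0.056 to 0.22).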

How the results depend on the processing

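Identifiers summed by symbol, also with each library left out, lists tested in the dose difference between gates and lists with each library left out were chosen after seeing the data, and the other alternatives were planned. With DESeq2 size factors, or without the 300 ng/ml libraries, each of the 8 counts of called genes stayed within 1.5 times its value. With 3 doses averaged 4056 genes were called between the gates. With no filter on low counts (23824 genes tested, not relied on) edgeR called 1566 and 1772 genes in SOX2-positive cells at 100 and 1000 ng/ml against control, 187 for dose in SOX2-positive and 1567 in SOX2-negative cells, and 412 for the dose difference between gates. DESeq2's Wald test called 1344, 1603, 18, 331 and 25 in the same order. With only the compared groups fitted edgeR called 2183, 1673, 0, 6 and 0, and 1509 in SOX2-negative cells at 100 ng/ml against control (396 and 792 genes at an unadjusted p under 0.05 where 0 were called). Limma-trend called 3 for dose in SOX2-positive and 1 in SOX2-negative cells. For these changes the cause was not tested. With identifiers summed edgeR called 0 genes for dose in SOX2-positive cells and 0 for the dose difference between gates (293 and 1349 at an unadjusted p under 0.05), since the call had been 1 of the copies of ATF6B.

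With the repeat as a block edgeR called 0 genes for the dose difference between gates (1094 at an unadjusted p under 0.05). It called 3781 between the gates, 622 and 797 in SOX2-positive cells and 3094 and 2759 in SOX2-negative cells against control, and 1 and 0 for dose. Besides calls of MIXL1, TBXT and NANOG the block brought 6 camera calls, among them the neuromesodermal and caudal list in SOX2-positive cells at 100 ng/ml (adjusted p = 0.069 without and 0.049 with it), the Nodal pathway (0.1 and 0.039) and mitochondrially encoded genes (0.069 and 0.039) there at 1000 ng/ml. The others were for the neural progenitor list in SOX2-negative cells at 100 ng/ml (0.054 and 0.044), the dissociation stress list there at 1000 ng/ml (0.084 and 0.03) and mitochondrially encoded genes in the dose difference between gates (0.07 and 0.038). The block changed no other call of a list or named gene.

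Leaving out 1 library at a time, with the library left in its group assumed to vary like the other groups, the counts ran over 2388 to 6512 between the gates, 39 to 107 and 60 to 404 in SOX2-positive cells at 100 and 1000 ng/ml against control, 1142 to 6649 and 1155 to 1827 in SOX2-negative cells, 0 to 2 and 0 to 5327 for dose in SOX2-positive and SOX2-negative cells and 0 to 3290 for the dose difference between gates. The cause was not tested. Of the outcomes of 235 fold changes of named genes over all alternatives, 2759 stayed on their side of the threshold, 256 lost and 49 gained the call, and none turned direction except BTBD7 between the gates, at -0.16 on the log2 scale summed over its identifiers and 11.59 for 1 of them kept apart, as fitted on libraries with no count. On leaving out a library 63 camera outcomes of lists lost and 26 gained the call, while 985 stayed on their side. HOX groups 10 to 13 had no gene to test without WNT3A 1000 SOX2-negative replicate 2. For dose in SOX2-positive cells the FGF target list turned from higher to lower and the forebrain list from lower to higher without WNT3A 1000 SOX2-positive replicate 1 (adjusted p = 0.38 and 0.6, over all left-out libraries 4.9e-06 to 0.71 and 4.9e-06 to 0.95). An estimated correlation ended 90 of the camera calls. A pseudocount alternative, meant for normalized values, was not run. The library totals limit what can be said of the rarest genes, such as SOX1, which with 3 counts over all libraries was below the filter and not tested.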

Other observations

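The tests of SOX2-negative cells in the SOX2-positive gate and of lists with a library left out were chosen only after the results were seen, and the count of splits was planned. In SOX2-negative cells, genes of further lists differed from control. In the neuromesodermal and caudal list 9 and 11 of 15 genes rose at 100 and 1000 ng/ml (10 and 11 higher adjusted over the list alone, camera adjusted p = 5e-05 and 1.2e-05, adjusted p = 0.27 and 0.18 with an estimated correlation). Among them CDX2 rose from 0.0184 ± 0.0260 to 4.66 ± 0.583 and 17.5 ± 0.708 CPM, and FGF17 from 0.688 ± 0.325 to 67.9 ± 16.8 and 92.4 ± 102 CPM. In the BMP list 6 and 6 of 13 rose and 1 and 0 fell (8 and 6 higher, 1 and 0 lower adjusted over the list alone, camera adjusted p = 0.012 and 0.015, adjusted p = 0.27 and 0.24 with an estimated correlation). The ligand BMP2 was at 238 ± 19.4 and 269 ± 24.9 against 13.6 ± 2.85 CPM. The retinoic acid list had 3 and 3 of 9 lower, the synthesis enzyme ALDH1A2, the catabolic enzyme CYP26C1 and DHRS3, and 1 and 1 higher, the retinol transporter STRA6 (1 and 1 higher, 3 and 3 lower adjusted over the list alone, camera adjusted p = 0.47 and 0.13). In the glycolysis and hypoxia list 7 and 8 of 16 rose and 1 and 0 fell (12 and 8 higher, 1 and 0 lower adjusted over the list alone, camera adjusted p = 3.4e-05 and 0.00042, adjusted p = 0.27 and 0.22 with an estimated correlation). The glucose transporter SLC2A3 was at 1689 ± 64.7 and 2258 ± 28.4 against 284 ± 57.0 CPM. The cell cycle list had 0 called by edgeR, 1 by DESeq2, 0 by limma-trend and 1 at an unadjusted p under 0.05 at 100 ng/ml. The replication genes MCM2 and MCM5 fell at 1000 ng/ml (0 and 2 lower adjusted over the list alone, camera adjusted p = 0.24 and 0.084). The cell cycle list gained a camera call at 100 ng/ml without SOX2-negative replicate 2 (adjusted p = 0.045). It also gained a camera call at 1000 ng/ml without SOX2-negative replicate 2 (adjusted p = 0.042). The retinoic acid list gained a camera call at 1000 ng/ml without SOX2-negative replicate 1 (adjusted p = 0.038). FGF17 lost the call at 100 ng/ml on leaving out either control library (edgeR adjusted p = 0.084 to 0.097). FGF17 lost the call at 1000 ng/ml on leaving out either control library (edgeR adjusted p = 0.075 to 0.081), and MCM2 on leaving out control replicate 2 or either SOX2-negative library (adjusted p = 0.056 to 0.12). MCM5 lost the call at 1000 ng/ml on leaving out either control library or SOX2-negative replicate 2 (edgeR adjusted p = 0.1 to 0.2).

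In SOX2-positive cells genes of the endoderm list went both ways. SOX17 and FOXA2 rose at both doses and GATA6 at 1000 ng/ml, while PRDM1 and SHISA2 fell at both and HHEX at 1000 ng/ml (2 and 3 of 11 higher and 4 and 3 lower, 4 and 3 higher, 4 and 4 lower adjusted over the list alone, camera adjusted p = 0.35 and 0.94). HHEX and, at 1000 ng/ml, SHISA2 were named after their values were seen. PRDM1 stood at 30.3 ± 0.295 CPM in control against 1.74 ± 0.353 and 2.07 ± 0.0832 CPM. In the midbrain and hindbrain list LMX1B and IRX3 fell at both doses (2 and 2 of 11 lower, 2 and 2 lower adjusted over the list alone, camera adjusted p = 0.044 and 0.044, adjusted p = 0.33 and 0.32 with an estimated correlation). That list lost its camera call at 100 ng/ml without control replicate 2 or SOX2-positive replicate 1 (adjusted p = 0.054 to 0.096). It also lost its camera call at 1000 ng/ml without control replicate 2 or SOX2-positive replicate 1 (adjusted p = 0.082 to 0.11). SOX17 lost the call at 100 ng/ml on leaving out either control library or SOX2-positive replicate 2 (edgeR adjusted p = 0.062 to 0.12), and FOXA2 without control replicate 2 or SOX2-positive replicate 1 (adjusted p = 0.056 to 0.13). SHISA2 and LMX1B lost the call at 100 ng/ml without any 1 of the 4 libraries (edgeR adjusted p = 0.058 to 0.21), and IRX3 on leaving out either control library or SOX2-positive replicate 1 (adjusted p = 0.068 to 0.11). SOX17 and FOXA2 lost the call at 1000 ng/ml without control replicate 2 (edgeR adjusted p = 0.054 to 0.073), and GATA6, SHISA2, HHEX, LMX1B and IRX3 on leaving out either control library or SOX2-positive replicate 1 (adjusted p = 0.053 to 0.2).

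In an edgeR fit to the 8 libraries at 100 and 1000 ng/ml, 3180 genes were called between the gates. Of 35 splits of these libraries into 4 and 4, only the real one gave as many, the highest other 2. Only the 8 that part each pair of gates from the same colonies can weigh chance. These are too few for a share under 0.05, so chance stays open. Among them the highest other gave 0, and the splits by dose and repeat, outside them, 0 and 0. All but the real one hold the gate difference as spread, so low counts were built in and test neither dose nor repeat.

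Of 11 streak genes 4 and 5 were called higher in SOX2-positive cells than in control at 100 and 1000 ng/ml (camera values above). The sort may have left some SOX2-negative cells there. For EOMES, EVX1, FOXA2, APLNR and GATA6 the rise over control stood at a median of 2.34, 1.77, 4.16 and 3.56% of that in the SOX2-negative library of the same colonies (WNT3A 100 replicates 1 and 2, WNT3A 1000 replicates 1 and 2), and for other genes abundant in SOX2-negative cells (at least 50 CPM and 20 times control) at 3.96, 2.38, 11.6 and 3.55%. The ratio of the medians was 0.358 to 1, under the 2 that would have spoken against carry-over. The other genes may themselves be raised in SOX2-positive cells, so the ratio cannot decide. SOX17 stood at only 0.363 to 2.49% and EOMES at 4.28 to 14.4%, below the upper quartile of those other genes, 5.92 to 31.8%, in each library, so carry-over, also of cells low in SOX17, and streak genes in cells that still hold SOX2 stay open. The response of SOX2-positive cells to the treatment, which the design names, was not tested apart from carry-over or the sort. Nor were this gate's dose differences in lists.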
